A study of Macaca fascicularis with 18 samples.

How the data were processed

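Gene expression was measured in nasal scrapes of 9 cynomolgus macaques (Macaca fascicularis). Per the labels, each animal gave 1 mock sample from the left nostril and 1 sample from the right nostril that received poly I:C, a synthetic double-stranded RNA, at 100 µg, so treatment and nostril cannot be told apart. The series text gives the dose with another unit, and the unit of the sample labels was used. The collection time is not given in the sources used here. Per the labels' protocols, total RNA was labelled for Affymetrix 3' expression arrays, and the probe annotation is that of a human array, so macaque RNA was hybridised to probes designed on human transcripts.

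The deposited values are log2 expression per probe set, made with RMA, per the submitters' processing notes; the version is not given in the sources used here. The table holds 7037 probe sets on 18 arrays, with values from 1.40 to 12.59 and array medians from 5.61 to 5.87. How these probe sets were chosen is not given in the sources used here. The lowest maximum of a probe set over the arrays was 4.73, as a filter on the highest value could leave. Such a filter could admit a gene dim in mock through its poly I:C arrays alone. For every probe set, the mean of an animal's 2 arrays was the same in all 9 animals, with a largest spread of 1e-04. The level of each animal had therefore been removed before deposit, and the deviations of an animal's 2 arrays from the group means correlated at -1 in every animal. Standard deviations within the mock and the poly I:C group are equal by this construction, so differences within animals are given with their error and n. The number of arrays limits the precision.

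The fit written down before the data were examined had treatment as its only term. With the animal means removed, that fit counts 16 residual degrees of freedom where 8 exist. The fit used throughout is therefore the linear model of limma with the animal as a fixed block. This change was made after the values were seen, and both counts are reported. The choice was checked on simulated data for poly I:C against mock, with 200 of 4677 genes changed in 5 runs. With the block, 53.1% of changes of 0.5, 91.6% of changes of 1 and 99.7% of changes of 2 on the log2 scale were recovered, and 5.37% of the calls were false. Without the block 50.9% of the calls were false.

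Of the probe sets, 6424 had 1 gene symbol, 213 had several, 395 were not listed in the annotation and 5 were controls. Probe sets with 1 symbol were reduced to 4677 genes, each represented by the probe set with the highest mean over all 18 arrays. Symbols are those of the array's annotation, and list members were matched to them by symbol or by an older symbol. The genomic span of 4501 genes (96.2%) was taken, by symbol, from a table of macaque genes (assembly T2T-MFA8v1.1). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with eBayes, two-sided. Lists of genes were fixed before the data were examined: 33 lists, of which 25 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01. A list's score is its mean log2 expression on an array. Scores were compared with a two-sided exact sign-flip permutation test over the 9 differences within animals, whose smallest possible p is 0.0039, and adjusted over the 25 lists.

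Named genes follow a rule set before the data were examined: the 12 largest rises and 8 largest falls among called genes moving the same way in at least 7 of 9 animals, up to 3 members of each list with the smallest p, and a fixed set of antiviral and inflammatory genes where measured. Alternatives were quantile normalization, centring of each array on its median, leaving out genes below the 25th percentile of mean expression, the mean of a gene's probe sets, every probe set as its own row, trend and robust eBayes, array weights, a fold threshold of 1.5, other set tests, other ways to build a score and leaving out each animal. The fit without the block, set before the data were examined, is kept as an alternative. A fit without animals 1 and 2, the ciliated cell score as a covariate, removal of a trend with gene span and a fit on the genes with a span alone were added after the values were seen. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.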

Results

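Nasal epithelial scrapes of 9 cynomolgus macaques were profiled on 18 arrays, 9 mock and 9 treated with 100 µg poly I:C, a synthetic double-stranded RNA that cells sense as they would a viral RNA. The comparison asks which transcripts changed with poly I:C within an animal. All changes are poly I:C minus mock on the log2 scale. For genes, the SE, moderated across genes by eBayes, and the adjusted p are those of limma with the animal as a block.

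The 3 largest rises were those of genes of the antiviral interferon response. IFIT2, an interferon-induced inhibitor of viral translation, rose by 3.29 ± 0.21 (SE, n = 9; adjusted p = 6.7e-06), from a mean of 4.82 to 8.11. IFNL1, a type III interferon that acts on epithelial cells, rose by 2.75 ± 0.17 (adjusted p = 6.7e-06), from a mean of 2.69 to 5.44. No measure of background was used here, so the sizes of rises from such low mock levels are uncertain. OASL rose by 2.45 ± 0.20 and RIGI, a cytosolic sensor of double-stranded RNA, by 1.63 ± 0.16. IFI44 rose by 1.54 ± 0.22 and ISG15, a ubiquitin-like modifier, by 1.05 ± 0.11. Each of these 6 genes was higher in the poly I:C sample of all 9 animals.

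**Figure D1:**
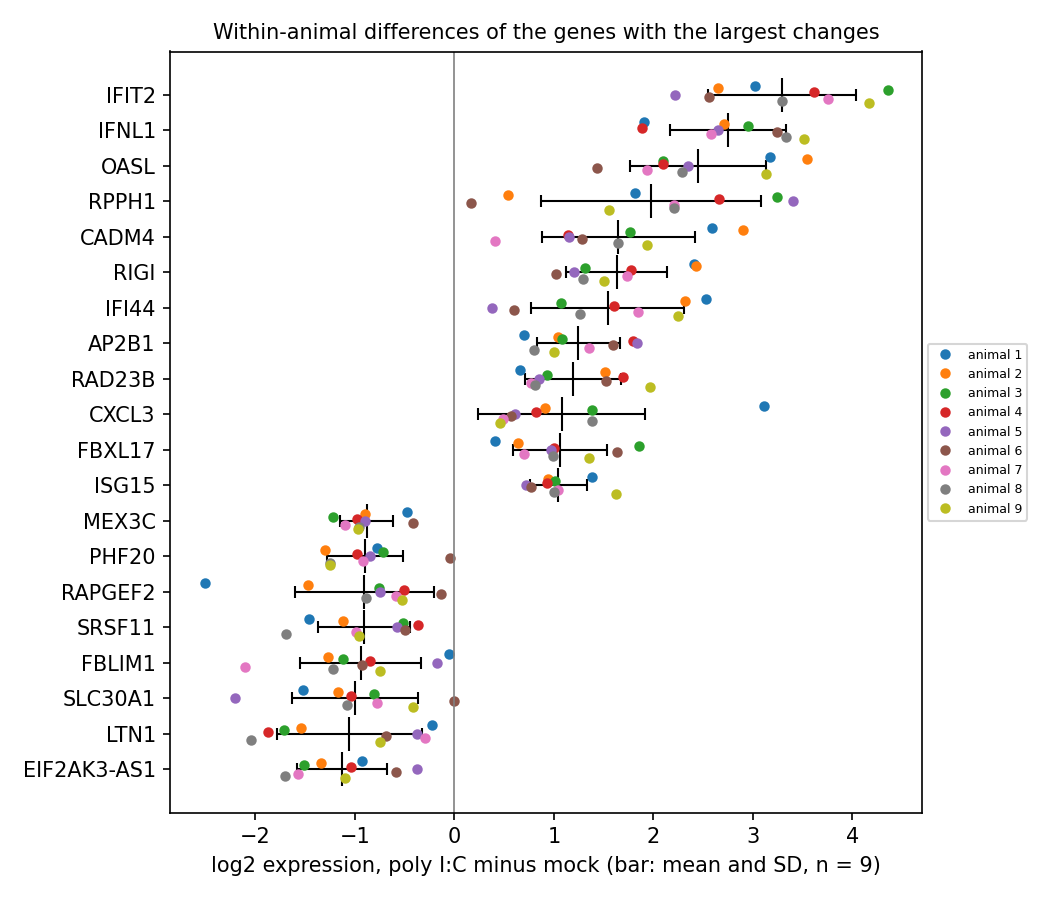
Within-animal differences in log2 expression (x axis, poly I:C minus mock) of the 12 genes with the largest rises and the 8 with the largest falls, 1 point per animal, with a tick for the mean and a bar for the SD over 9 animals. IFIT2 has the largest mean, 3.29, and the CXCL3 difference of animal 1 is 3.11.

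In all, 357 of 4677 genes passed the threshold, of which 91 were higher and 266 lower with poly I:C. With each array centred on its median 191 were higher and 137 lower, and with quantile normalization 172 were higher and 161 lower, so the balance of rises and falls follows the scaling. All 91 rises were kept under both scalings, and 137 and 160 of the falls. Both scalings raised the median change of all genes, from -0.06 to 0.03 and 0.01. They thus favour rises over falls, so the kept rises are no test of robustness to scaling. Without the animal block 1543 genes passed. The count was 102 without animal 3, 171 without animal 4, 213 without animal 6, 138 without animal 7 and 118 without animal 8.

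Among the 22 measured of 72 listed interferon-stimulated genes 6 rose, none fell and 16 did not pass. The same 6 passed when adjusted over the list alone. The members rising were IFIT2, OASL, RIGI, ISG15, IFI44 and 1 other gene. Of the 22, 20 had a difference above 0, but the median change was 0.17, so the score rests largely on the called members. Camera placed the list above other genes (adjusted p = 2.51e-08; adjusted p = 0.53 with an estimated correlation). The score of the list was higher by 0.58 ± 0.32 (SD, n = 9) in the poly I:C sample, in 9 of 9 animals, from 0.27 to 1.08 (exact sign-flip permutation p = 0.0039, the smallest possible; adjusted p = 0.049 over 25 lists). IFNL1 was the sole measured member of the interferon list. Under a filter on the highest value, OASL and IFNL1 (mock means 4.01 and 2.69) could have entered the table through their poly I:C arrays alone. Such a filter would favour rises of such genes, and of the interferon-stimulated score, which holds OASL. TLR3, IFIH1, DHX58, IFNB1, CXCL10 and MX1 were not analysed here. Of 12 measured genes of RNA sensing and interferon signalling RIGI rose and 11 did not pass (camera adjusted p = 0.081). Among those 11, AZI2 was at -0.27 ± 0.12 and IRF5 at 0.26 ± 0.13.

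Of 9 guanylate-binding and interferon-gamma-type genes 2 rose, GBP2 by 0.77 ± 0.15 and WARS1, a tryptophanyl-tRNA synthetase, by 0.60 ± 0.14. Adjusted over the list alone 5 rose. APOL1 differed by 0.41 ± 0.12 without passing over all genes (adjusted p = 0.054). The list's score was higher in 9 of 9 animals, by 0.38 ± 0.32 (SD, n = 9; exact sign-flip permutation p = 0.0039, the smallest possible; adjusted p = 0.049). Camera gave an adjusted p of 2.15e-05 and an adjusted p = 0.53 with an estimated correlation. WARS1 no longer passed without animal 3 (0.62, limma adjusted p = 0.061), 4 (0.62, 0.057), 5 (0.57, 0.059) or 8 (0.59, 0.071).

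Of 14 measured genes of MHC class I antigen processing 1 rose, CALR, a chaperone of the endoplasmic reticulum, by 0.71 ± 0.15 (adjusted p = 0.020; 0.053 without animal 3, with a change of 0.63). HLA-C differed by 0.45 ± 0.16 and HLA-E by 0.34 ± 0.13 without passing, and by 0.29 and 0.22 without animal 1. The other probe set of HLA-E was at 0.056. The list had a camera adjusted p of 2.15e-05 and an adjusted p = 0.53 with an estimated correlation. Its mean change of 0.29 was 0.19 without animal 1. Among members with a known span, which leave out HLA-B, HLA-C, HLA-E, HLA-F and HLA-G, it was 0.23, and 0.17 with the span trend removed. Of 8 MHC class II genes none passed (camera adjusted p = 0.74).

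Of 10 measured chemokines 1 rose, CXCL3, a neutrophil attractant, by 1.08 ± 0.24 in 9 of 9 animals (adjusted p = 0.023). It no longer passed without animal 3 (1.04, limma adjusted p = 0.061) or animal 8 (1.04, 0.063). Adjusted over the list alone 2 rose. CCL20 differed by 0.75 ± 0.22 (adjusted p = 0.058) and CXCL8 by 0.32 ± 0.19 (adjusted p = 0.33). Camera gave the list an adjusted p of 0.0021, and an adjusted p = 0.53 with an estimated correlation. The chemokine score differed by 0.30 ± 0.54 (SD, n = 9, exact sign-flip permutation p = 0.13, adjusted p = 0.31) and by 0.15 without animal 1. Fits limited to genes with a known span leave out CXCL3, CXCL2 and CCL4. There the mean change of the chemokines was 0.20 (camera adjusted p = 0.048), and 0.12 with the span trend removed (camera adjusted p = 0.12). None of 14 cytokines passed, with CSF3 at 0.41 ± 0.12, IL23A at 0.64 ± 0.25 and IL6 at 0.49 ± 0.26 (camera adjusted p = 8.88e-04; adjusted p = 0.53 with an estimated correlation). None of 18 NF-kappaB targets passed, with PTX3 at 0.75 ± 0.27 (camera adjusted p = 9.2e-04; adjusted p = 0.62 with an estimated correlation). The cytokine and the NF-kappaB scores each had an exact sign-flip permutation adjusted p of 0.31. Animal 1 weighed heavily on the chemokine, cytokine and NF-kappaB lists. Without it the mean change of the cytokines was 0.16 in place of 0.33 and that of the NF-kappaB targets 0.08 in place of 0.22, the second no longer called (camera adjusted p = 0.079), while IL6 was at 0.28, CXCL8 at 0.17 and PTX3 at 0.49.

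The chemokine score moved with leukocyte transcripts from animal to animal. Across the 9 animals the differences of the chemokine and the pan-leukocyte scores had Pearson's r = 0.93 (permutation p = 6.89e-05, adjusted p = 3.45e-04 over 5 relations) and Spearman's rho = 0.97 (permutation p = 1.65e-04, adjusted p = 8.27e-04). Without animals 1 and 9 Pearson's r was 0.90. These 5 relations were chosen after the values were seen.

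**Figure D2:**
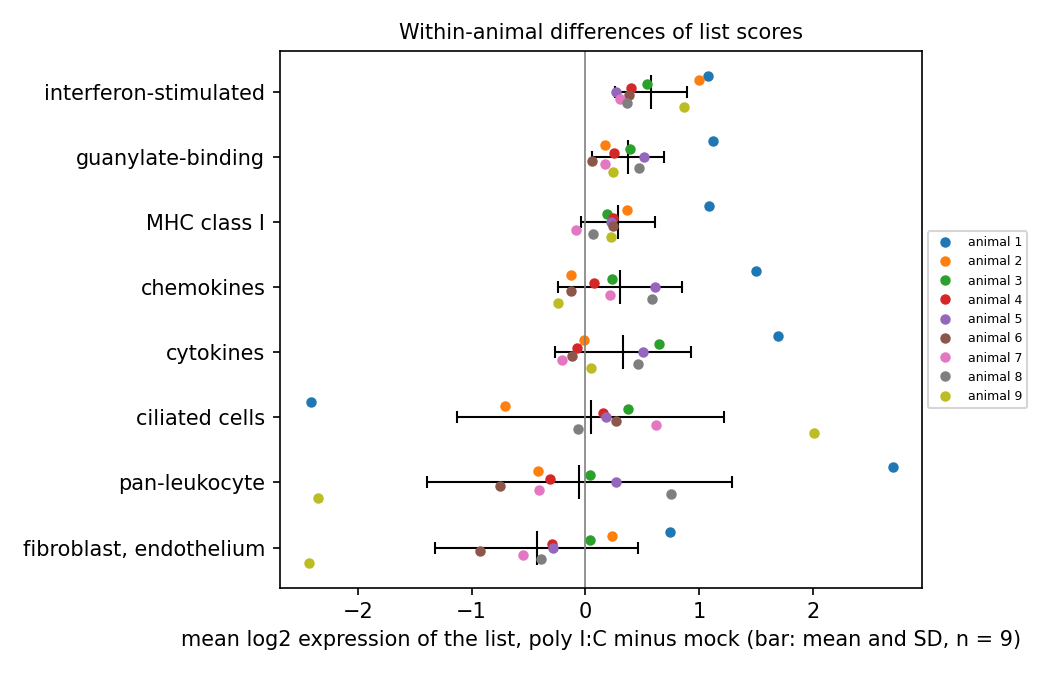
Differences of the mean log2 expression of 8 gene lists (x axis, poly I:C minus mock), 1 point per animal, with a tick for the mean and a bar for the SD over 9 animals. The interferon-stimulated score is above 0 in all 9 animals, while the ciliated cell score runs from -2.42 in animal 1 to 2.01 in animal 9.

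No marker of a cell type that a scrape can hold passed the threshold. None of 38 ciliated cell genes passed, and the ciliated score differed by 0.05 ± 1.17 (SD, n = 9; exact sign-flip permutation p = 0.86), with FOXJ1, the regulator of motile cilia, at 0.23 ± 0.11. The pan-leukocyte score, from 5 genes, differed by -0.05 ± 1.34 (SD, n = 9; exact sign-flip permutation p = 0.85). None of 22 secretory and goblet cell, 11 gland, 14 basal or 16 squamous genes passed, nor any of 8 genes of fibroblasts and endothelium, among them DCN at -1.56 ± 0.57 (adjusted p = 0.11), or of 5 of neutrophils and mast cells. No T, NK, B or plasma cell gene was analysed here. None passed among 2 olfactory, 4 monocyte and macrophage, 1 erythrocyte or 1 cell cycle gene. The erythrocyte gene, HBB, was at -0.84 ± 0.28 (adjusted p = 0.091).

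Among 21 genes of junctions and the epithelial barrier PKP3, a desmosome plaque protein, rose by 0.75 ± 0.14 and CLDN4, a tight junction claudin, by 0.40 ± 0.10, while TJP1, a tight junction scaffold, fell by 0.56 (SE 0.12). With the mean of its probe sets TJP1 was at -0.26 (limma adjusted p = 0.35). Without animal 3 or animal 8 TJP1 was at -0.57 and -0.50 (limma adjusted p = 0.050 and 0.053). CLDN4 no longer passed without animal 3 (0.36), 4 (0.37), 6 (0.40) or 8 (0.38). With the gene span trend removed, a fit added after the values were seen, neither CLDN4 (0.29, limma adjusted p = 0.097) nor TJP1 (-0.45, 0.051) passed. In the other lists single genes passed. DAXX of the cell death list rose by 0.61 ± 0.16, IER5 of 24 immediate-early and heat shock genes by 0.47 ± 0.12, GSTA1 of 15 xenobiotic metabolism genes by 0.40 ± 0.09 and NDUFB5 of 31 oxidative phosphorylation genes by 0.52 ± 0.14. PDK1 of 15 hypoxia and glycolysis genes fell by 0.43 (SE 0.10). These 5 calls ended on leaving out single animals: animals 1, 3, 5, 6, 7, 8 or 9 for DAXX (0.57 to 0.66), animals 1, 2, 3, 4, 6, 7 or 8 for IER5 (0.41 to 0.52), animals 3, 4, 7 or 8 for GSTA1 (0.37 to 0.42), any animal but 1 for NDUFB5 (0.44 to 0.57) and animals 3, 5, 7 or 8 for PDK1 (-0.42 to -0.38). With the span trend removed DAXX (0.52), IER5 (0.37), NDUFB5 (0.48) and PDK1 (-0.36) did not pass, and without animals 1 and 2 DAXX (0.45) and IER5 (0.43) did not. Adjusted over the list alone IER5 and NDUFB5 did not pass, and in the cell death list 2 of 8 genes rose and 1 fell. The oxidative phosphorylation list had 24 of 31 members above 0 (camera adjusted p = 2.18e-04; adjusted p = 0.53 with an estimated correlation). Its score had an exact sign-flip permutation adjusted p of 0.21. The list's mean change of 0.12 was 0.08 without animal 9 and 0.06 with the span trend removed. It was 0.19 with quantile normalization and 0.21 with each array centred on its median. None passed among 8 cholesterol synthesis, 15 unfolded protein response, 4 ribosomal protein or 9 ion transport genes.

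Outside these lists, RPPH1, the RNA of RNase P, rose by 1.98 ± 0.31 and CADM4, an adhesion molecule, by 1.65 ± 0.22. AP2B1, an adaptor of clathrin coats, rose by 1.25 ± 0.14, RAD23B, a DNA repair factor, by 1.19 ± 0.15 and FBXL17 by 1.06 ± 0.15. The other probe sets of CADM4 and RAD23B had mean changes of 0.15 and -0.09. The largest falls were those of EIF2AK3-AS1 at -1.13 ± 0.14, LTN1, a ubiquitin ligase of stalled ribosomes, at -1.05 ± 0.21, SLC30A1, a zinc exporter, at -0.9999 ± 0.19 and FBLIM1 at -0.94 ± 0.18. SRSF11, RAPGEF2, PHF20 and MEX3C fell by 0.91, 0.90, 0.90 and 0.88. LTN1 no longer passed without animal 3 (-0.97, limma adjusted p = 0.051). RAPGEF2 no longer passed without animal 3 (-0.92), 7 (-0.94) or 8 (-0.90). With the mean of all probe sets of a gene RAPGEF2 was at -0.52 (limma adjusted p = 0.10), PHF20 at -0.56, CADM4 at 0.65 and RAD23B at 0.55, the last 3 still passing. RAPGEF2 was at -0.59 without animals 1 and 2, a fit added after the values were seen. All 8 were lower in the poly I:C sample of 9 of 9 animals.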

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

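The tests on cell makeup, swapped labels, single probe sets and the unequal split after removal of the span trend were chosen after the values were seen. Of 36 sets of 9 differences, 3 held 1 animal far from the others, where chance gives about 1.8. In animal 1 the chemokine score differed by 1.505, against -0.24 to 0.61 in the others, and CXCL3 by 3.11, against 0.45 to 1.39. In animal 6 PHF20 differed by -0.0463, against -1.30 to -0.71. Of 608 probe sets with several gene symbols or none, which the comparisons leave out, 11 rose and 23 fell.

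More genes fell (266) than rose (91). With each array centred on its median 41.8% of the calls were falls, but centring draws the median change of all genes towards 0 by construction (-0.06 before, 0.03 after), so an offset between arrays and a true excess of falls cannot be told apart. A trend with gene span was judged by the falls still called after its removal, with bounds fixed before that share was known. It was 66.1%, between the bounds for and against the trend, so that test left the trend open for the single falls. A second test, chosen once its value was known, found that 74.5% of the calls were still falls after removal of the trend. That removal kept the offset of each array, so this share decides nothing about the trend. A true excess of falls with poly I:C, or with the nostril, stays open.

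The differences of animals 1 and 9 pointed opposite ways along ciliated and leukocyte genes. Mock and poly I:C labels swapped within an animal are argued against by the interferon-stimulated score, which was higher in the poly I:C sample of 9 animals. The score does not test an exchange of samples between animals. A different cell makeup of the 2 scrapes of an animal is a candidate explanation: the ciliated and pan-leukocyte differences had Pearson's r = -0.91 (permutation p = 0.0091, adjusted p = 0.015) and Spearman's rho = -0.60 (permutation p = 0.097, adjusted p = 0.16). Without animals 1 and 9 r was -0.07, so this relation rests on those animals. Other cell lists varied in other animals too: the squamous score differed by -1.29 in animal 6 and by 1.48 in animal 2. The basal score ran from -0.69 in animal 5 to 0.81 in animal 2. SRGN, the brightest of the 5 pan-leukocyte genes (mean log2 6.92), differed by 4.64 in animal 1 and by -1.37 in animal 9, and PTPRC, the leukocyte surface antigen CD45, by 3.69 and -3.37.

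For 18 genes outside the lists that rose and have another probe set, the called probe sets had a median change of 0.48 and the others 0.16, against -0.06 over all genes. The value lies between the bounds for and against a signal of single probe sets. Of the 18, 11 moved the same way, against 893 of 1262 among all genes with over 1 probe set. Of the falls outside the lists 85 of 98 did, where the median change of all genes was also below 0. The rises of genes such as CADM4 and RAD23B cannot be told apart from signals of single probe sets.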

How the results depend on the processing

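The fits without animals 1 and 2, with the ciliated score, without the span trend and on genes with a span alone were chosen after the values were seen. Against 357 genes (91 higher, 266 lower), the fit with no replicate block, set before the data were examined, called 1543 (506 and 1037), because it counts residual degrees of freedom that the animal pairs do not hold. The replicate block with array weights gave 716 (175 and 541), the ciliated score as a covariate 670 (186 and 484), every probe set as its own row 548 (138 and 410) and a fold threshold of 1.5 4 (4 and 0). Quantile normalization moved the split to 172 and 161, and centring on the array median to 191 and 137. Without animals 1 and 2 147 genes were higher. Leaving out 1 animal gave 102 to 365 genes, 33 to 82 higher and 69 to 288 lower, with fewer residual degrees of freedom. Of 7 lists, 0 passed camera with an estimated correlation and 2 passed fry's directional test; leaving out 1 animal gave 7 to 8. The interferon-stimulated score kept an unadjusted p under 0.05 in every alternative, at 0.52 to 0.62 on leaving out 1 animal, where the smallest possible p is 0.0078, or 0.098 adjusted over 25 lists with 2 of them at it. The chemokine score had an unadjusted p under 0.05 as the median of the list (0.51) and in the unpaired test with no replicate block (0.30). That unpaired test counts an animal's 2 arrays as independent, which they are not, so its p is no support for a rise. On leaving out 1 animal the chemokine score ran from 0.15 to 0.37. The ciliated score was -0.059 as a median and 0.51 without animals 1 and 2, which have its lowest values, so that this is no test of a rise; it ran from -0.20 to 0.36. The pan-leukocyte score was 0.0147 with quantile normalization and 0.0051 with the mean of probe sets, and ran from -0.40 to 0.23. Except where stated, the cause was not tested. For called named genes, 460 of 517 pairs of a gene and an alternative held the call and 57 lost it. These pairs include the fit with no replicate block, which kept all 357 calls. They also include the fit on genes with a span alone, which repeats the main fit on fewer genes and kept 338 of 339. The mean of probe sets leaves the values of a gene with a single probe set unchanged. Such pairs could hardly lose a call, so the 460 overstate how far the calls held. The pairs leave out centring on the array median, the filter on dim genes, every probe set as its own row, trend and robust eBayes, and the fold threshold. No measure of background is used here, so whether low levels lie above it stays open. The animal as a random block was not run, since the correlation within animals was at its limit of -0.99.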

Other observations

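The tests on relations across animals and on gene span by animal were chosen after the values were seen. Longer genes had lower changes with poly I:C. In 5 equal groups of genes by genomic span, with a median of 4.91 kb in the shortest and 158.7 kb in the longest, the median change went from 0.01 to -0.16. In the shortest group 28 genes rose and 13 fell, and in the longest 8 rose and 96 fell. Spearman's rho of span and difference, across genes, which are not independent replicates, was below 0 in 9 of 9 animals, from -0.24 to -0.02 (exact sign-flip permutation p = 0.0039, the smallest possible). The ACTB control probe sets give a 5' minus middle difference, a sign of RNA quality. The poly I:C minus mock change of that difference averaged -0.07 over the 9 animals (exact sign-flip permutation p = 0.12).

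Among 100 splits that part every pair, only 1, the real one, gave as many genes, 357 against at most 1 in the others. This argues against chance for the number of genes called, to the limit of 1 in 100 that the splits allow. The other splits set 2 to 4 animals against the rest. Chance cannot be excluded for the number of lists called by camera: 74 of the 100 splits gave 7 lists or more, and the highest gave 18. The preset correlation of camera is a candidate explanation, since 0 lists passed with an estimated correlation.

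The relations of ciliated with fibroblast and endothelium scores (Pearson's r = -0.88, permutation p = 0.0079, adjusted p = 0.015; Spearman's rho = -0.73, permutation p = 0.031, adjusted p = 0.078; r = -0.59 without animals 1 and 9), of ciliated with interferon-stimulated scores (r = -0.41, permutation p = 0.31; rho = -0.35, permutation p = 0.36; r = -0.81 without animals 1 and 9) and of chemokine with interferon-stimulated scores (r = 0.18, permutation p = 0.66; rho = -0.17, permutation p = 0.68; r = -0.57 without those animals) complete the 5 computed.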
